A study of Rattus norvegicus with 11 samples.

How the data were processed

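Total RNA from rat lung alveolar epithelial cells was measured on 11 Affymetrix rat expression arrays. Per the sample descriptions, 4 arrays held RNA from freshly isolated type I (TI) cells, 4 from freshly isolated type II (TII) cells and 3 from cultured TII cells. The titles give day 0 for the fresh cells and day 7 for the culture. The groups were taken from the descriptions and titles, because the source field reads isolated TI cells for all 11 arrays. The labels name a cDNA synthesis kit and biotin labelling. The labels do not say whether the arrays of a group came from separate animals, so every p-value below measures only the spread between these arrays.

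The deposited table gives 1 value per probe set and array, on a log2 scale, as processed by the authors. How probe signals were summarised, background corrected and normalized is not given in the sources used here. The log base was read from the values: the highest value, 13.16, would stand for an intensity of 520737 if it were a natural logarithm, above the 65535 that a 16-bit scanner records, and for 9172 on a log2 scale. Array medians lay between 5.43 and 5.51 and upper quartiles between 6.65 and 6.73, so the arrays were already on a common scale and the values were used as deposited. Of 8799 probe sets, 59 control probe sets were kept apart, and 8740 were tested with no filter on dim signal. The probe annotation gave exactly 1 gene for 7006 of these, several genes for 308 and none for 1426. For results per gene, the probe set with the highest mean over all arrays stood for the gene, which gave 4736 genes. Genes are named by symbol, with Entrez gene identifiers from the probe annotation where printed. Genome coordinates were not given in the sources used here. Precision is limited by the number of arrays, 3 or 4 per group.

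A linear model with 3 group means was fitted to all 11 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. The 3 comparisons were fresh TI minus fresh TII, cultured TII minus fresh TII, and fresh TI minus cultured TII. P-values were adjusted by the Benjamini-Hochberg method over the 8740 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The number at least 2-fold apart was counted beside it. A gene was called specific to a group when it was higher, or lower, than in each of the other groups at that threshold. The 25 gene lists were written from textbook knowledge of the alveolar epithelium and of the other cells a lung isolate can hold. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. Members called were also counted with p-values adjusted over the list alone. The relation between the change in culture and the TI difference was measured across genes by Pearson r and slope. Because both share the fresh TII arrays, it was recomputed with separate pairs of fresh TII arrays as the controls, over 6 splits, and in 100 simulated data sets with no change.

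The groups, the comparisons, the lists and the rule for naming genes were set before the data were examined. The rule named, per comparison, the 10 genes with the highest and the 10 with the lowest log2 difference among called genes whose arrays did not overlap between the groups. It also named the called members of the type I and type II lists, up to 4 called members of each other list with the greatest absolute difference, and 5 genes per group and direction among the group-specific genes. Unless stated otherwise, values are log2 differences with the standard error from the model, with n = 4 fresh TI, 4 fresh TII and 3 cultured TII arrays.

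The procedure was tested on simulated data in which 200 of 8740 probe sets were changed. For fresh TI minus fresh TII it recovered 82.1% of 1.5-fold changes and 100% of 2-fold changes, with 9 false calls among 197. For cultured TII minus fresh TII it recovered 73.1% and 94.0%, with 11 false calls among 189. In 20 simulated data sets with no list moved, 3 list calls were made in all. Genes were drawn there with no correlation, so this does not measure false list calls among correlated genes.

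Alternatives were quantile normalization, median centring, leaving out the dimmer probe sets at 2 levels, an intensity trend or a robust fit in eBayes, fits on 2 groups, array weights, the replicate number as a block, an adjusted p under 0.01, the mean or the other probe sets of a gene, and leaving out each array in turn. Matching the standard deviation of the arrays was added after seeing the data. Replicate numbers were not used to pair arrays: deviations from the group means correlated between -0.20 and 0.28 for the 10 pairs of arrays with the same number, and between -0.27 and 0.23 for the 30 pairs with different numbers. Control probe sets were compared with exact permutation tests (scipy 1.17.1, two-sided), adjusted over the family of tests.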

Results

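Gene expression was compared between the cell types that line the rat alveolus: the flat TI cells that cover most of its surface, and the cuboidal TII cells that make surfactant. The arrays measured 8740 probe sets in 4 samples of freshly isolated TI cells, 4 of freshly isolated TII cells and 3 of TII cells on day 7 of culture. Signal ran from 1.37 to 13.16 (log2). The arrays of a group resembled each other: Pearson r across probe sets was 0.995 to 0.998 among fresh TII, 0.986 to 0.993 among cultured TII and 0.978 to 0.996 among fresh TI arrays. Between groups r was 0.913 to 0.947. The first principal component held 47.7% of the variance and placed fresh TII arrays apart from both other groups, and the second held 40.4% and placed cultured TII arrays apart from fresh TI arrays.

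The comparison of fresh TI with fresh TII cells asked which genes set the alveolar cell types apart in the lung. Some listed markers of each type separated them widely, while others given below differed little. Podoplanin (Pdpn, Entrez gene 54320), a surface glycoprotein of TI cells, was higher in fresh TI cells by 4.48 ± 0.08 (log2, SE), a 22.3-fold difference. The water channel Aqp5 (25241) was higher by 4.30 ± 0.23, caveolin Cav1 (25404) by 3.75 ± 0.17 and the receptor Ager (81722) by 3.08 ± 0.12. Among the 10 lowest genes, the chitinase Chia (113901) differed by -4.86 ± 0.15 and the phospholipase Pla2g1b (29526) by -4.29 ± 0.23. They are not on the type II list and are named for the size of this difference. The mucin Muc1 (24571), which is on that list, differed by -4.03 ± 0.23. The surfactant protein genes Sftpb (192155) and Sftpa1 (24773) differed by -3.27 ± 0.30 and -3.22 ± 0.47.

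In all, 4783 of 8740 probe sets were called, 2996 higher and 1787 lower in fresh TI cells. Of these, 199 were at least 2-fold higher and 456 at least 2-fold lower. The groups did not overlap for 50.7% of probe sets, against 2.86% by chance. The median probe set was 0.13 (log2) higher in fresh TI cells, 0.17 in the dimmest of 5 brightness classes and -0.10 in the brightest, and matching the spread of the arrays brought the overall median to 0.04. With that, 2252 probe sets were called higher and 2005 lower, and without the probe sets dimmer than the median 1337 and 1334, so the excess of higher calls depends on the scaling and on dim probe sets. Small differences are therefore to be read against that shift. After quantile normalization 654 of the 655 probe sets at least 2-fold apart stayed called in the same direction. That step moved the overall median only to 0.069, so it could hardly end such calls. It does not clear wide differences of an effect of the scaling.

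Of 14 measured genes on the type I list, 10 were higher and 2 lower in fresh TI cells (adjusted p = 0.000115; adjusted p = 0.216 with an estimated correlation). The counts were the same adjusted over the list alone. Besides Pdpn, Aqp5, Cav1 and Ager, the members included the anchoring protein Akap5 at 3.24 ± 0.19, Icam1 at 1.08 ± 0.09, Sec14l3 at 1.03 ± 0.30, the growth factor Vegfa at 0.97 ± 0.07, the basement membrane collagen Col4a3 at 0.85 ± 0.14 and Cyp4b1 at 0.48 ± 0.18. P2rx4 at -0.31 ± 0.12 and Gnb1 at -0.25 ± 0.10 were lower. Other probe sets stood at 2.11, 2.44 and 2.75 for Vegfa, and at -0.48 and, not called, -0.19 for Gnb1. Other genes among the 10 highest were Spock2, a matrix proteoglycan, at 4.70 ± 0.19, the small heat shock protein Cryab at 3.93 ± 0.13, the matrix cross-linking enzyme Lox at 3.48 ± 0.26, Rpl19l4 at 3.39 ± 0.10, the phospholipase Pla2g2a at 3.35 ± 0.21 and Crp at 3.23 ± 0.14. The Crp probe set carries a suffix for sequence shared by related transcripts, as does another at 3.31, while the Crp probe set without it differed by 0.35. Both names follow the probe annotation, and whether the Crp and Rpl19l4 signal came from these genes was not tested.

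Of 16 measured genes on the type II list, 12 were lower and 2 higher in fresh TI cells (adjusted p = 3.01e-05, and 0.0299 with an estimated correlation; 12 and 2 adjusted over the list alone). Sftpd, a collectin of the surfactant, differed by -1.81 ± 0.25 and Sftpc by -1.19 ± 0.29. Alkaline phosphatase Alpl differed by -2.50 ± 0.09, the protease Ctsc by -1.88 ± 0.15, the transcription factors Cebpd by -1.36 ± 0.19, Cebpa by -0.88 ± 0.08 and Nkx2-1 by -0.52 ± 0.11, Lyz2 by -0.85 ± 0.33 and Ctsh by -0.53 ± 0.08. The higher members were Slc34a1 at 0.23 ± 0.08 and Cftr at 0.18 ± 0.07. Another probe set was not called for Cebpd (0.12, beside one at -1.68), Cebpa (0.08), Nkx2-1 (-0.15) and Slc34a1 (0.14), of which those of Cebpd and Cebpa pointed the other way. Surfactant signal remained on the fresh TI arrays, at a mean of 11.9 for Sftpc, 9.35 for Sftpb, 8.96 for Sftpa1 and 9.62 for Sftpd. It differed between those arrays, by 1.78 for Sftpc, 1.82 for Sftpb and 2.62 for Sftpa1, against 0.56 for Sftpd.

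**Figure D1:**
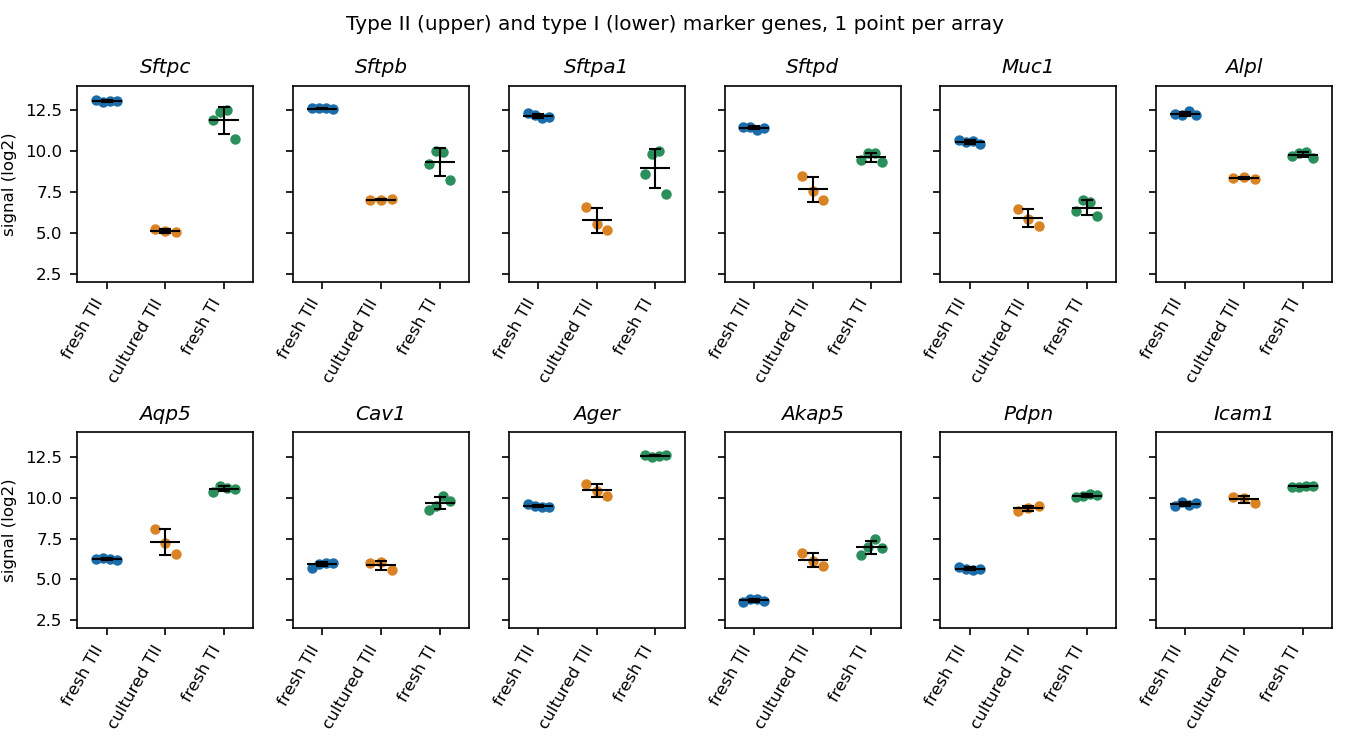
Signal (log2, vertical axis) of 6 type II list genes (upper panels) and 6 type I list genes (lower panels) on the 4 fresh TII, 3 cultured TII and 4 fresh TI arrays. Each point is an array, the horizontal mark is the group mean and the bar is the SD; Pdpn lay at 5.66 in fresh TII, 9.35 in cultured TII and 10.1 in fresh TI cells, while Sftpc lay at 13.1, 5.12 and 11.9.

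Of 23 genes of fatty acid and phospholipid synthesis 14 were lower and 3 higher in fresh TI cells (adjusted p = 3.51e-06, and 0.0243 with an estimated correlation). Among them were the desaturase Scd at -3.68 ± 0.21, Acsl4 at -2.82 ± 0.09, fatty acid synthase Fasn at -2.80 ± 0.10 and Acly at -2.33 ± 0.15. Another probe set stood at 0.16, not called, for Acsl4 (beside one at -3.27), -0.91 for Acly and -1.92 for Scd. Of 14 genes of cholesterol synthesis 11 were lower and 0 higher (adjusted p = 2.02e-06, and 0.00976 with an estimated correlation), including Idi1 at -3.34 ± 0.16, Insig1 at -2.60 ± 0.09, Sqle at -2.40 ± 0.13 and Msmo1 at -2.21 ± 0.21. Another probe set stood at -0.58 for Idi1 and -1.23 for Msmo1. The lowest adjusted p at the preset correlation was that of immediate early and stress genes, with 26 of 36 lower and 1 higher (adjusted p = 1.47e-13, and 0.00976 with an estimated correlation). Among them were the transcription factors Egr2 at -3.51 ± 0.14, Atf3 at -3.45 ± 0.15, Nr4a1 at -2.66 ± 0.12 and Myc at -2.54 ± 0.09. Adjusted over the list alone, the counts of these 3 lists were the same.

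Extracellular matrix genes were higher in fresh TI cells, 26 of 35 with 0 lower, also adjusted over the list alone (adjusted p = 7.44e-06, and 0.00976 with an estimated correlation). The list median was 0.51 against 0.11 for all genes. Lox, the laminin chain Lama3 at 2.92 ± 0.13, Col3a1 at 2.52 ± 0.47 and fibronectin Fn1 at 2.26 ± 0.13 were the furthest apart. Other probe sets gave less: 0.14, 0.31, 0.34 and 0.90 for Fn1, and 0.75, 0.94 and 1.23 for Lox. The list of fibroblast and smooth muscle markers moved with it: 11 of 19 were higher and 0 lower, or 12 and 0 adjusted over the list alone (adjusted p = 0.00404; adjusted p = 0.319 with an estimated correlation). They included elastin Eln at 1.82 ± 0.20 and Fbln5 at 2.33 ± 0.11, and 9 of the 19 stand on another list too. Whether TI cells or other cells in the isolate gave the matrix signal was not tested. Annexin and S100 genes were higher for 10 of 14 and lower for 1, or 11 and 1 adjusted over the list alone (adjusted p = 0.00681; adjusted p = 0.352 with an estimated correlation). They ran from S100a9 at 1.77 ± 0.31 and S100a4 at 1.65 ± 0.29 to the calcium-binding protein S100g at -4.06 ± 0.32. Cytoskeletal genes were higher for 16 of 32 and lower for 4, also adjusted over the list alone (adjusted p = 0.049; adjusted p = 0.439 with an estimated correlation). Members included moesin Msn at 1.86 ± 0.15, vimentin Vim at 1.76 ± 0.42, Rhob at -1.56 ± 0.16 and Krt18 at -1.34 ± 0.22. Another Msn probe set, at 0.14, was not called. The cytoskeletal call also ended with the mean of all probe sets of a gene and with the replicate number as a block.

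The list of endoplasmic reticulum chaperones, which also holds stress response genes, was lower in fresh TI cells for 12 of 16 genes and higher for 2, also adjusted over the list alone (adjusted p = 0.000115; adjusted p = 0.237 with an estimated correlation). Lower ones were the chaperone Dnajb9 at -1.56 ± 0.17 and the stress-induced transcription factor Ddit3 at -1.42 ± 0.12. Of 44 genes of xenobiotic and glutathione metabolism 23 were lower and 15 higher, also adjusted over the list alone (adjusted p = 0.00312; adjusted p = 0.415 with an estimated correlation). The lower ones included the cytochrome Cyp2f4 at -4.07 ± 0.09, Aldh1a1 at -3.09 ± 0.21, Ephx1 at -3.03 ± 0.15 and Gsta1 at -2.97 ± 0.13. Cyp2f4 and Aldh1a1 are on the airway list too, and the airway marker Scgb1a1 moved with them, at -3.31 ± 0.13. Of 28 genes of oxidative phosphorylation 14 were lower and 2 higher, with 15 lower adjusted over the list alone (adjusted p = 0.000476; adjusted p = 0.439 with an estimated correlation). That call also ended after quantile normalization and after matching the spread of the arrays.

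The other lists were not called for fresh TI minus fresh TII. Of 27 genes of ion and water transport 12 were higher and 7 lower (adjusted p = 0.936), with Aqp5 at one end and Kcnj15 at -2.60 ± 0.14, the sodium pump subunit Atp1b1 at -2.43 ± 0.13 and Slc12a2 at -2.43 ± 0.16 at the other. Another Slc12a2 probe set was called the other way, at 0.30, with 2 more at -1.10 and -1.52, and other Atp1b1 probe sets stood at -0.77 and -3.33. Junction genes were higher for 4 of 11 and lower for 6 (adjusted p = 0.138), with claudin Cldn3 at -2.41 ± 0.16. Antigen presentation genes were higher for 13 of 23 and lower for 8 (adjusted p = 0.888), with RT1-Da at -1.98 ± 0.45 and Irf1 at -2.16 ± 0.16 (-1.37 on another Irf1 probe set). Leukocyte and macrophage markers were higher for 10 of 28 and lower for 1 (adjusted p = 0.107), and endothelial markers for 7 of 15 and 1 (0.189). The counts were, for mesothelial markers, 3 of 4 and 0 (0.189), for airway markers, 5 of 12 and 4 (0.683), and for red blood cell markers, 2 of 5 and 2 (0.886). Integrins were higher for 2 of 7 and lower for 1 (0.886), and cell division genes for 7 of 24 and 6 (0.774). The same counts were, for TGF-beta response genes, 6 of 19 and 7 (0.244), for insulin-like growth factor genes, 5 of 14 and 2 (0.546), and for glycolysis genes, 3 of 18 and 5 (0.271). Adjusted over the list alone, these counts were the same. The median and the mean differed in sign for cell division (0.06 and -0.10), antigen presentation (0.20 and -0.14), TGF-beta response (0.003 and -0.23), airway (0.21 and -0.70) and red blood cell (0.05 and -0.33) genes.

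The comparison of cultured with fresh TII cells asked how the cells changed by day 7 of culture. The transcripts of surfactant proteins fell: Sftpc (50683) by 7.97 ± 0.31 (log2, SE) from 13.1, near the highest value on the arrays, Sftpa1 by 6.42 ± 0.51, Sftpb by 5.58 ± 0.32 and Sftpd by 3.76 ± 0.27. Among the other genes that fell most were the defensin Defb4 by 7.46 ± 0.39, the chemokine Cxcl3 by 7.22 ± 0.54, Pla2g1b by 5.92 ± 0.25 and Chia by 5.42 ± 0.17. Osteopontin Spp1 (25353), a secreted matrix phosphoprotein, rose by 7.05 ± 0.25, from a mean of 2.89 to 9.94. Fibronectin Fn1 (25661) rose by 5.68 ± 0.14, the actin-binding protein Tagln (25123) by 5.03 ± 0.12, Wfdc1 by 4.81 ± 0.15 and Lox by 4.39 ± 0.28.

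In all, 2918 probe sets were called, 1669 higher and 1249 lower in culture, with 389 at least 2-fold higher and 369 at least 2-fold lower. The groups did not overlap for 43.3% of probe sets, against 5.71% by chance. The median probe set differed by -0.01. The 3' minus 5' signal of the beta-actin control, a measure of RNA quality, moved with this comparison. It was -0.33 to -0.08 on the cultured and 0.32 to 0.43 on the fresh TII arrays, with no overlap. The difference was -0.53 (exact permutation p = 0.0571, adjusted p = 0.0857). The GAPDH control moved the same way, by -0.13, with the same p and adjusted p. Its arrays did not overlap either, at 0.30 to 0.45 on the cultured and 0.47 to 0.57 on the fresh TII arrays. A p of 0.0571 is the lowest that 3 against 4 arrays can give, so the adjusted p does not speak against a difference. The bearing of RNA quality on the calls was not tested.

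Of 16 type II list genes 11 fell and 1 rose (adjusted p = 1.1e-07, and 0.0126 with an estimated correlation; 12 fell adjusted over the list alone). Besides the surfactant genes, Muc1 fell by 4.67 ± 0.25, Alpl by 3.90 ± 0.09, Lyz2 by 2.46 ± 0.36, Ctsc by 1.33 ± 0.16, Nkx2-1 by 1.22 ± 0.12, Cebpa by 0.97 ± 0.09 and Cftr by 0.25 ± 0.08. The cathepsin Ctsh rose by 0.72 ± 0.09. The type I list was not called (adjusted p = 0.327), with 6 of 14 higher and 3 lower, also adjusted over the list alone. Pdpn rose by 3.69 ± 0.08, Akap5 by 2.47 ± 0.21, Aqp5 by 1.03 ± 0.25, Ager by 0.95 ± 0.13, Vegfa by 0.74 ± 0.08 and Icam1 by 0.29 ± 0.10. Sec14l3 fell by 4.07 ± 0.33, Cyp4b1 by 3.44 ± 0.19 and Gnb1 by 0.30 ± 0.10, although another Gnb1 probe set stood at 0.95. Other probe sets were not called for Aqp5 (0.55) and Cebpa (-0.007), and stood at -0.37 for Nkx2-1 and at 1.64, 1.71 and 2.32 for Vegfa. Cav1 differed by -0.06 ± 0.18 (adjusted p = 0.86), and its sign turned with array weights.

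Extracellular matrix genes rose for 19 of 35 and fell for 4, or 21 and 4 adjusted over the list alone (adjusted p = 9.46e-06, and 0.0126 with an estimated correlation). They were led by Spp1, Fn1, Lox and Lama3 at 3.27 ± 0.14. Other probe sets rose by 2.08 to 3.95 for Fn1 and by 1.14 to 2.64 for Lox. Cytoskeletal genes rose for 18 of 32 and fell for 4, also adjusted over the list alone (adjusted p = 0.000139; adjusted p = 0.213 with an estimated correlation). Caldesmon Cald1 rose by 3.82 ± 0.18, tropomyosin Tpm1 by 2.47 ± 0.16 and Vim by 2.42 ± 0.45. Other Tpm1 probe sets stood at 2.31, 0.94, 0.37 and, not called, 0.03. The fibroblast and smooth muscle markers rose for 6 of 19 and fell for 1, or 8 and 2 adjusted over the list alone (adjusted p = 0.0186; adjusted p = 0.37 with an estimated correlation). Among them were Fbln5 at 3.18 ± 0.12 and the proteoglycan Bgn at 2.63 ± 0.10. The cell cycle inhibitor Cdkn2b rose by 3.42 ± 0.12 and the secreted chaperone Clu by 3.39 ± 0.12.

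Of 28 genes of oxidative phosphorylation 17 rose and 1 fell, or 19 and 1 adjusted over the list alone (adjusted p = 3.93e-05; adjusted p = 0.372 with an estimated correlation). These included the ADP carrier Slc25a4 at 1.06 ± 0.12 and Cox8a at 0.84 ± 0.08 (0.41 to 0.62 on others). Of 18 glycolysis genes 10 rose and 1 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.00519; adjusted p = 0.284 with an estimated correlation). The highest were Pfkp at 2.24 ± 0.32 (1.004 on another Pfkp probe set), Aldoa at 1.87 ± 0.10 and Pgam1 at 1.76 ± 0.07. Of 16 genes on the chaperone list 12 rose and 2 fell, or 12 and 3 adjusted over the list alone (adjusted p = 9.72e-05; adjusted p = 0.213 with an estimated correlation). Among them were the disulfide isomerases Pdia4 at 2.22 ± 0.09 and Pdia6 at 1.42 ± 0.10 and Calu at 1.76 ± 0.08.

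Immediate early and stress genes fell for 25 of 36 and rose for 1, also adjusted over the list alone (adjusted p = 1.06e-14, and 0.0126 with an estimated correlation): Nr4a1 by 4.22 ± 0.13, Egr2 by 3.90 ± 0.16, Atf3 by 3.68 ± 0.16 and Egr1 by 3.50 ± 0.16 (1.62 on another Egr1 probe set). Genes of fatty acid and phospholipid synthesis fell for 10 of 23 and rose for 2, or 11 and 2 adjusted over the list alone (adjusted p = 0.00602; adjusted p = 0.213 with an estimated correlation). These included Scd at -4.72 ± 0.22 (-1.98 on another Scd probe set) and Fasn at -2.40 ± 0.11. Cholesterol synthesis genes fell for 4 of 14 and rose for 0, also adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.053 with an estimated correlation), with Idi1 at -2.84 ± 0.18 (-1.12 on another Idi1 probe set). Xenobiotic and glutathione genes fell for 23 of 44 and rose for 5, or 25 and 5 adjusted over the list alone (adjusted p = 1.08e-05; adjusted p = 0.213 with an estimated correlation). The steepest included Cyp2f4 at -4.39 ± 0.10 and the sulfotransferase Sult1a1 at -4.04 ± 0.13. Airway markers fell for 4 of 12 and rose for 0, also adjusted over the list alone (adjusted p = 0.00223; adjusted p = 0.284 with an estimated correlation). They were Cyp2f4, Aldh1a1 at -3.54 ± 0.23, Scgb1a1 at -2.62 ± 0.14 and Foxj1 at -0.38 ± 0.11.

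The other lists were not called for cultured minus fresh TII. Antigen presentation genes fell for 9 of 23 and rose for 5 (adjusted p = 0.139), with the invariant chain Cd74 at -3.62 ± 0.32, RT1-Da at -4.20 ± 0.48 and the protease Ctss at 2.97 ± 0.44. Junction genes rose for 4 of 11 and fell for 5 (0.791), with the gap junction protein Gja1 at 2.96 ± 0.15, Epcam at 1.72 ± 0.14 and Cldn3 at -2.46 ± 0.18. Leukocyte and macrophage markers rose for 6 of 28 and fell for 4 (0.791), with the chemokine Ccl2 at 3.09 ± 0.22 and the lectin Lgals3 at 2.38 ± 0.42. Red blood cell markers fell for 3 of 5 and rose for 0 (0.0594), with the haemoglobin genes Hbb at -3.49 ± 0.37 and Hbb-b1 at -1.73 ± 0.33. Transport genes rose for 3 of 27 and fell for 8 (0.266), annexins and S100 proteins for 6 of 14 and 3 (0.327), and integrins for 2 of 7 and 1 (0.599). Cell division genes rose for 8 of 24 and fell for 5 (0.629), and TGF-beta response genes for 4 of 19 and 5 (0.909). For insulin-like growth factor genes the counts were 2 of 14 and 3 (0.406), for endothelial markers 1 of 15 and 1 (0.599), and for mesothelial markers 0 of 4 and 0 (0.789). Adjusted over the list alone, these counts were the same except that 6 TGF-beta response genes rose. The median and the mean differed in sign for transport (0.006 and -0.16), junction (-0.02 and 0.12), leukocyte and macrophage (-0.09 and 0.28) and endothelial (-0.07 and 0.01) genes.

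**Figure D2:**
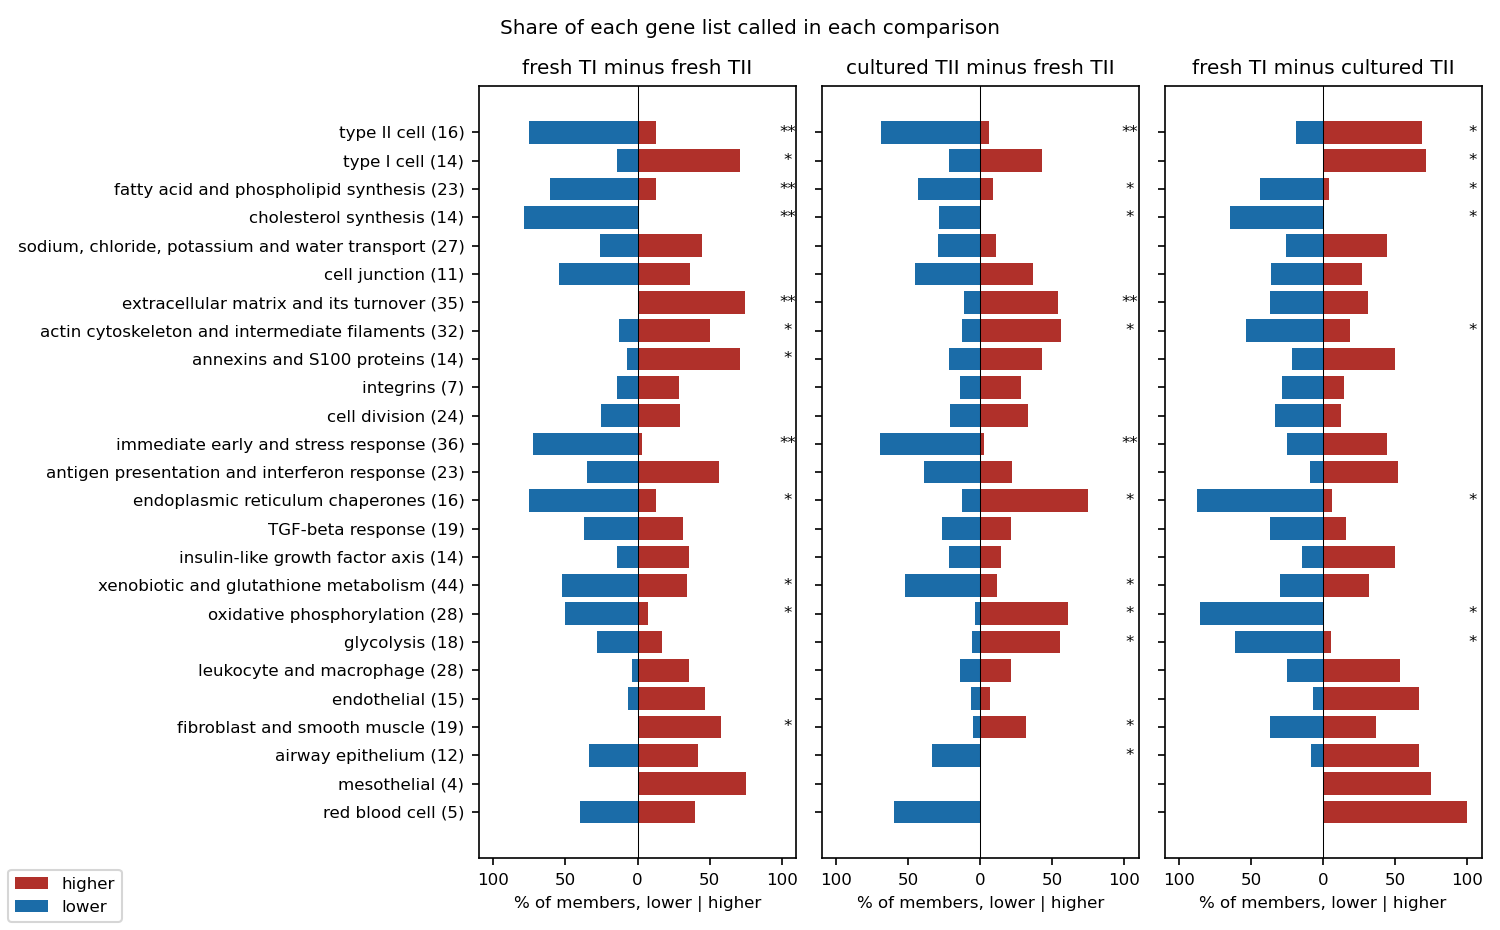
Share of the measured members of each gene list (number in brackets) called higher (right, red) or lower (left, blue) in each of the 3 comparisons, in percent. An asterisk marks a list called at an adjusted p under 0.05 with the preset correlation, and a double asterisk a list also called with an estimated correlation, as for 12 of 16 type II list genes lower in fresh TI cells.

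Cultured TII cells are widely used as a stand-in for TI cells, and the 2 changes were compared gene by gene. Of 95 genes at least 2-fold higher in fresh TI than in fresh TII cells, 56 were also higher in culture, 11 were lower and 28 were not called. Of 237 genes at least 2-fold lower in fresh TI cells, 173 were also lower in culture, 15 were higher and 49 were not called. Pdpn, Akap5, Lox, Lama3, Cryab and Wfdc1 were higher in both, and Chia, Pla2g1b, Muc1, Scd and the surfactant genes lower in both. Counting every called gene, 422 were lower in both against 140.8 if the calls were independent, and 295 were higher in both against 321.2. With separate fresh TII arrays as controls, those counts were 335 to 355 lower and 180 to 191 higher in both, against 85.6 to 104.9 and 147.5 to 196.6 expected. The number higher in both was above its expectation in 4 of these 6 splits. In the opposite direction, 59 genes were higher in fresh TI cells and lower in culture, against 219.7 expected, and 212 were lower in fresh TI cells and higher in culture, against 205.9. With separate controls these were 24 to 43 and 111 to 170, against 101.7 to 130.3 and 125.0 to 157.1 expected. Across 4736 genes, which are not independent replicates, Pearson r was 0.53 with a slope of 0.61, and Spearman rho was 0.19. With separate controls r averaged 0.52, between 0.49 and 0.55, and the slope 0.60. Simulated groups with no change that shared the controls also gave r = 0.46 and a slope of 0.50, but a covariance of 0.01 against 0.24 observed. Separate controls remove shared noise only: a trait of the fresh TII cells alone would still enter both differences. Immediate early and stress genes were lower than in fresh TII cells for 26 of 36 in fresh TI and 25 of 36 in cultured cells. The correlation alone therefore cannot tell a move towards TI cells from the loss of such a trait.

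**Figure D3:**
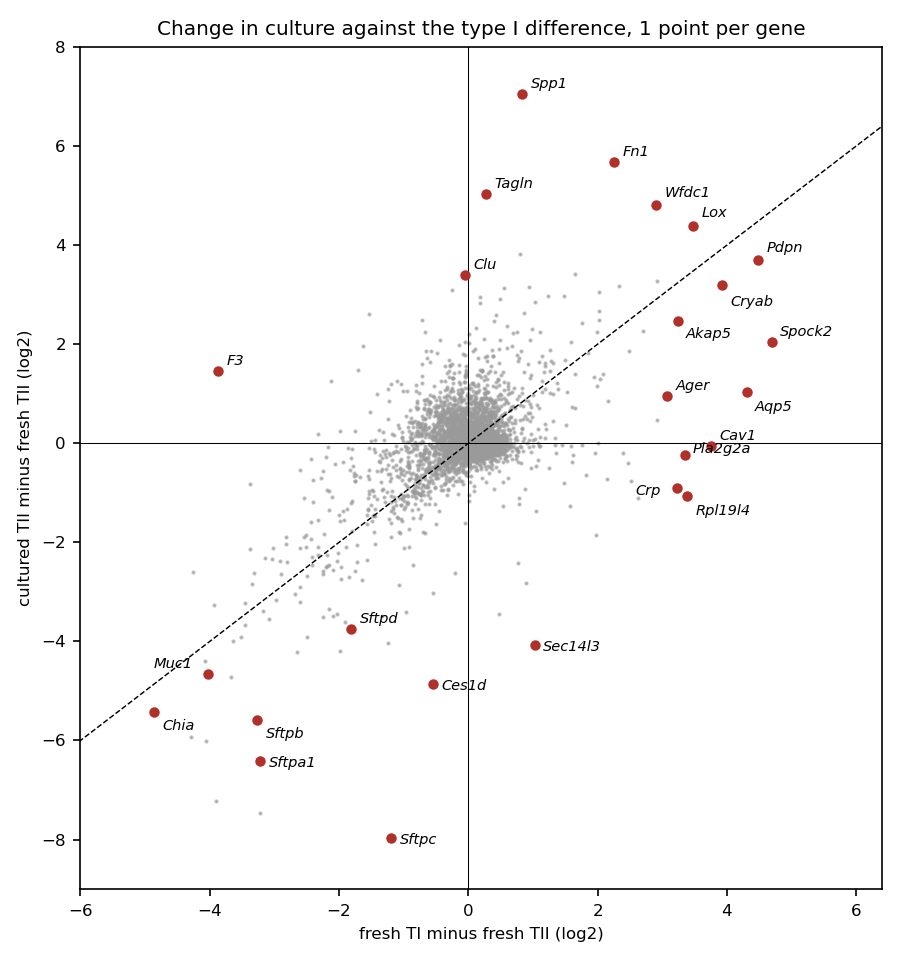
Change in culture (cultured TII minus fresh TII, log2, vertical axis) against the difference between cell types (fresh TI minus fresh TII, log2, horizontal axis), with 1 point for each of 4736 genes and selected genes in red. The dashed line marks equal change; Pdpn at 4.48 and 3.69 lies near it, whereas Cav1 at 3.75 and -0.06 does not, and Spp1 rose by 7.05 in culture against 0.83 for fresh TI cells.

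The direct comparison of fresh TI with cultured TII cells asked where the culture and the TI cell of the lung differ. Among the genes furthest above the cultured cells in fresh TI cells were Sftpc at 6.77 ± 0.31 (log2, SE), the lipid-binding protein Sec14l3 at 5.10 ± 0.33, the carboxylesterase Ces1d at 4.30 ± 0.20, Cyp4b1 at 3.92 ± 0.19 and Cyp2b2 at 3.82 ± 0.22. TI markers were also higher in fresh TI cells, Cav1 at 3.81 ± 0.18, Aqp5 at 3.27 ± 0.25 and Ager at 2.13 ± 0.13, with smaller differences for Pdpn at 0.79 ± 0.08 and Akap5 at 0.77 ± 0.21. Cultured cells had more Spp1, at -6.22 ± 0.25, tissue factor F3 at -5.33 ± 0.12, Tagln at -4.75 ± 0.12, kininogen Kng2 at -4.15 ± 0.11 and the growth factor Areg at -3.58 ± 0.12.

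In all, 5235 probe sets were called, 3124 higher and 2111 lower in fresh TI cells, with 211 at least 2-fold higher and 571 at least 2-fold lower. The groups did not overlap for 57.3% of probe sets, against 5.71% by chance. The median probe set was 0.13 higher in fresh TI cells, and 0.02 with the spread of the arrays matched. The 3' minus 5' control signal differed as well, by 0.50 for beta-actin (exact permutation p = 0.0571, adjusted p = 0.0857) and 0.16 for GAPDH (0.1143 and 0.1371). For beta-actin the arrays did not overlap, and 0.0571 is the lowest p that 4 against 3 arrays can give. The bearing of this signal on the calls was not tested. With the spread matched the majority turned, to 2294 higher and 2323 lower, as it did without the probe sets dimmer than the median, at 1375 and 1618.

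Of 8 lists called here, 0 held with an estimated correlation. The type I list was higher for 10 of 14 genes and lower for 0 (adjusted p = 0.000768; adjusted p = 0.279 with an estimated correlation), and the type II list for 11 of 16 and 3 (adjusted p = 0.0394; adjusted p = 0.279 with an estimated correlation). The type II members lower in fresh TI cells were Ctsh at -1.25 ± 0.09, Cebpd at -0.81 ± 0.20 (0.04, not called, on another Cebpd probe set) and Ctsc at -0.55 ± 0.16. Genes of oxidative phosphorylation were lower in fresh TI cells for 24 of 28 and higher for 0 (adjusted p = 5.26e-09; adjusted p = 0.279 with an estimated correlation). Their list median was -0.68 against 0.11 for all genes. Genes of the chaperone list were lower for 14 of 16 and higher for 1 (adjusted p = 5.26e-09; adjusted p = 0.257 with an estimated correlation). They included Pdia3 at -2.40 ± 0.10 (-1.28 on another Pdia3 probe set) and Pdia4 at -2.20 ± 0.09. Glycolysis genes were lower for 11 of 18 and higher for 1 (adjusted p = 0.000768; adjusted p = 0.279 with an estimated correlation). Lower were the glucose transporter Slc2a1 at -2.51 ± 0.17 (-0.95 on another Slc2a1 probe set) and Aldoa at -2.46 ± 0.10. Cholesterol synthesis genes were lower for 9 of 14 and higher for 0 (adjusted p = 0.0196; adjusted p = 0.257 with an estimated correlation). Genes of fatty acid and phospholipid synthesis were lower for 10 of 23 and higher for 1 (adjusted p = 0.0282; adjusted p = 0.279 with an estimated correlation). Cytoskeletal genes were lower for 17 of 32 and higher for 6 (adjusted p = 0.0394; adjusted p = 0.417 with an estimated correlation). The last 2 calls also ended after quantile normalization. At the lower level of leaving out dim probe sets, those 2 calls and that of cholesterol synthesis ended. With the mean of all probe sets of a gene, the type II and cytoskeletal calls ended. Adjusted over the list alone, the counts of the 8 lists were the same except for 15 chaperone list genes lower and 2 glycolysis genes higher.

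The remaining lists were not called for fresh TI minus cultured TII. Matrix genes were higher for 11 of 35 and lower for 13 (adjusted p = 0.257; 11 and 16 adjusted over the list alone), with Col3a1 at 3.28 ± 0.50 (2.16 on another Col3a1 probe set) and Eln at 2.47 ± 0.21 opposite Spp1 and Fn1. Transport genes were higher for 12 of 27 and lower for 7 (0.346), including the water channel Aqp1 at 2.58 ± 0.20. Immediate early genes were higher for 16 of 36 and lower for 9 (0.346), antigen presentation genes for 12 of 23 and 2 (0.173), and xenobiotic genes for 14 of 44 and 13 (0.364). Annexins and S100 proteins were higher for 7 of 14 and lower for 3 (0.346), and insulin-like growth factor genes for 7 of 14 and 2 (0.225). The counts were, for TGF-beta response genes, 3 of 19 and 7 (0.18), for junction genes, 3 of 11 and 4 (0.292), for integrins, 1 of 7 and 2 (0.739), and for cell division genes, 3 of 24 and 8 (0.225). Markers of other cells were higher for 15 of 28 and lower for 7 among leukocytes and macrophages (0.193), 10 of 15 and 1 in endothelium (0.078), and 7 of 19 and 7 in fibroblasts and smooth muscle (0.577). They were higher for 8 of 12 and 1 in airway (0.0796), 3 of 4 and 0 in mesothelium (0.173), and 5 of 5 and 0 in red blood cells (0.113). Adjusted over the list alone, 3 antigen presentation genes were lower, 16 leukocyte genes and 4 mesothelial genes higher, and the other counts the same. The median and the mean differed in sign for integrins (0.16 and -0.12) and fibroblast genes (0.07 and -0.13).

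Each group was also set apart from both others by genes of its own. Of 4736 genes, 1064 were highest in fresh TI cells, 38 of them at least 2-fold against both other groups, led by Cav1, Rpl19l4, Pla2g2a, Aqp5 and Crp. The Crp probe set without the suffix for shared sequence was only 0.35 above fresh and 0.34 above cultured TII cells. Rpl19l4 has no other probe set to compare. In culture the Crp and Rpl19l4 probe sets fell, by 0.91 and 1.06. The control for the B1 repeat moved the same way, at 0.82 for fresh TI and -0.54 for cultured TII minus fresh TII. Whether the Crp and Rpl19l4 signal came from the named genes was not tested. The 1064 fell to 527 without the probe sets dimmer than the median and to 566 at an adjusted p under 0.01. Small differences among them are to be read against the median probe set, which was 0.13 higher in fresh TI cells in either comparison. Fresh TI cells were lowest for 612 genes, 67 at least 2-fold, led by F3, Tmeff1, Slc2a1, the haem oxygenase Hmox1 and Atp1b1. Fresh TII cells were highest for 422 genes, 131 at least 2-fold, led by Chia, Pla2g1b, Cyp2f4, S100g and Muc1. Cyp2f4 is also on the airway list, and airway cells in the TII isolate were not tested as its source. Fresh TII cells were lowest for 295, 46 at least 2-fold, led by Pdpn, Lox, Cryab, Lama3 and Wfdc1. Cultured TII cells were highest for 741 genes, 143 at least 2-fold, led by Spp1, Tagln, Fn1, Clu and Ccl2, and lowest for 311, 44 at least 2-fold, led by Sftpc, Ces1d, Defb4, Sec14l3 and Cyp4b1. The 311 became 184 at an adjusted p under 0.01 and 473 with array weights, and the 295 lowest in fresh TII cells became 170 at an adjusted p under 0.01.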

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

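All tests of an explanation in this part were chosen after the result was seen, except the counts over other splits of the arrays, whose bounds were set before those splits were run.

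Other splits of the arrays asked whether chance could give counts as large. For changed probe sets, 1 of 35 splits, the real one, gave as many calls in each comparison. No lower share is possible with 35 splits. The real split gave 4783 calls against a highest other of 0 for fresh TI minus fresh TII. It gave 2918 against 4 for cultured TII minus fresh TII. For fresh TI minus cultured TII, 5235 stood against 3533, from a split that exchanged 3 arrays. Splits that mix the groups put the group difference into the spread, so their low counts say little about chance. For group-specific genes, 1 of 100 drawn splits, the real one, gave as many as 3445, against a highest other of 437. For the number of lists called, the count over all splits does not exclude chance: 4 of 35 splits gave as many as 12 for fresh TI minus fresh TII (highest other 13), 4 of 35 gave as many as 12 for cultured TII minus fresh TII (highest other 12), and 14 of 35 gave as many as 8 for fresh TI minus cultured TII (highest other 11). Splits that exchange few arrays keep part of the real contrast: for fresh TI minus fresh TII, the 16 that exchanged 1 array gave 7 to 13 lists, and the 18 that exchanged 2 gave 0 to 3 against the real 12. The 18 that exchanged 2 arrays gave 1 to 8 against 12 for cultured TII minus fresh TII, and 0 to 10 against 8 for fresh TI minus cultured TII. In those comparisons, exchanging 1 array gave 6 to 12 and 4 to 11 lists. Exchanging 3 arrays, which nearly swaps the groups, gave 11 to 12 and 5 to 10.

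Surfactant signal on the fresh TI arrays is the first pattern weighed. TII cells mixed in at a single share would carry over every abundant TII transcript in proportion, and the list gene with the lowest ratio, Muc1, allows a share of 6.12%, while outside the list Pla2g1b allows 5.10% and Chia 3.44%. Sftpd would need 28.5% and lay above the brighter Sftpb, relative to fresh TII cells, on every fresh TI array, which argues against carry-over as its whole source. Sftpb would need 10.4%, Sftpa1 10.8% and Sftpc 43.8%, also above what Chia allows. These 3 lie at 12.6, 12.2 and 13.1 in fresh TII cells, within 1 log2 of the highest value, where a ceiling of the scale may hide part of the difference, so carry-over and expression by TI cells cannot be told apart for them, and 15 of the 16 measured type II list genes lie above the median gene in fresh TII cells.

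Macrophage genes on the cultured arrays are the next pattern. The 6 genes of the leukocyte and macrophage list that rose in culture (Ccl2, Lgals3, Cd53, Mmp12, Fcgr2b and Itgam) were all 6 lowest on cultured replicate 1 and highest on replicate 3, as were 26.4% of the 972 genes higher in culture. Because the order was seen in these genes, it was tested on the other 22 measured genes of the list: 13 had it, against 20.1% of all genes not higher in culture (exact hypergeometric p = 6.51e-05, one-sided, which treats genes as independent). Mmp12 lay at 3.46, 5.01 and 6.18 and Lgals3, the brightest, at 9.84, 10.9 and 11.1, consistent with macrophages at a share that differs between cultures, although the list as a whole was not called, 6 of its 28 genes lie above the median gene in fresh TII cells and 2 stand on another list. The range of Spp1 over the cultures was 0.84, against 0.66 for the dim Itgam, 0.93 for Ccl2, 1.31 for Lgals3, 1.94 for Cd53, 2.30 for Fcgr2b and 2.72 for Mmp12, and on replicate 1 Spp1 was already 6.57 above fresh TII cells, where Itgam, Mmp12 and Fcgr2b were 0.25, 0.47 and 0.55 above; with genes this far apart, macrophages and cultured TII cells cannot be told apart as its source, and a differing state of the cultured TII cells was not tested.

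The higher reading of dim probe sets on the fresh TI arrays, whose values also span a narrower range (SD 1.77 to 1.85 against 1.92 to 1.97), is the last pattern. Hybridization spikes read 0.71 (log2) higher on the fresh TI arrays than on the others (exact permutation p = 0.0061 over 330 splits, two-sided, not adjusted), consistent with less labelled sample, but against fresh TII alone the difference was 0.60 (exact p = 0.0571, adjusted p = 0.0857) and fresh TI replicate 3, at 8.88, lay below fresh TII replicate 1, at 9.08. RNA degradation is argued against for fresh TI minus fresh TII by the 3' minus 5' signal of beta-actin, at -0.038, and of GAPDH, at 0.03, but stays open for fresh TI minus cultured TII, at 0.50 and 0.16, where the GAPDH values of the arrays overlap (0.41 to 0.69 and 0.30 to 0.45). Of 655 probe sets at least 2-fold apart between fresh TI and fresh TII, 654 stayed called in the same direction after quantile normalization. That step moved the median difference only from 0.125 to 0.069, so differences this wide could hardly lose their call. For cultured minus fresh TII, 754 of 758 stayed called. The number at least 2-fold lower in fresh TI than in cultured TII cells fell from 571 to 461. The retained calls therefore do not test the amount of labelled sample, which is confounded with the cell type for small and wide differences alike.

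Samples far from the others of their group were sought in 412 sets of 4 arrays, and 15 were found where chance gives about 1 in 20, or 20.6. On fresh TI replicate 4, RT1-Da was lowest at 7.75 (others at least 8.85), RT1-Db1 at 6.92 (7.72 to 7.85), Cebpd at 6.10 (6.39 to 6.43) and Coro1a at 6.68 (7.84 to 7.96), and Aldh3a1 highest at 5.38 (5.08 to 5.12). On fresh TII replicate 3, Hbb was highest at 10.1 (8.36 to 8.52), Hbb-b1 at 9.65 (8.08 to 8.14) and Ccl3 at 6.43 (6.18 to 6.20), and Ephx1 lowest at 8.87 (9.20 to 9.24) and Sec14l3 at 9.23 (9.51 to 9.57). On fresh TII replicate 4, Sftpb was lowest at 12.59 (12.62 to 12.63) and Pgam1 at 9.04 (9.12 to 9.12). On fresh TII replicate 2, Pdia6 was lowest at 8.82 (8.96 to 8.97) and S100b highest at 6.42 (6.36 to 6.37), and on fresh TII replicate 1 Cdk4 was highest at 8.02 (7.75 to 7.77). Among control probe sets, which the comparisons leave out, the mid-transcript GAPDH probe set was 1.98 higher in cultured than in fresh TII cells, above every fresh TII array (9.65 to 9.78). The control for the B1 repeat was 0.82 higher in fresh TI than in fresh TII cells (5.18 to 5.30), with no overlap (exact permutation p = 0.0286, adjusted p = 0.0857). It was 1.36 higher in fresh TI than in cultured TII cells. Its relation to the higher reading of dim probe sets on the fresh TI arrays was not tested.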

How the results depend on the processing

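Matching the spread of the arrays was the alternative chosen after seeing the data. Without the probe sets dimmer than the median, which leaves fewer to test, 2671 were called for fresh TI minus fresh TII and 2993 for fresh TI minus cultured TII, and 527 genes were highest in fresh TI cells. At the lower of the 2 levels of leaving out dim probe sets, 1884 of 3430 calls were higher for fresh TI minus fresh TII and 1954 of 3815 for fresh TI minus cultured TII. At an adjusted p under 0.01, 1796 of 3210 and 2022 of 3780 were higher in those comparisons, and 2254 genes were group-specific, 566 highest in fresh TI, 170 lowest in fresh TII and 184 lowest in cultured TII cells. With array weights 473 genes were lowest in cultured TII cells, and the cause was not tested. With an estimated correlation, 8 of the 32 list calls held. The correlation of the change in culture with the TI difference was 0.587 over called genes and 0.565 over the brighter genes, where the slope was 0.664.

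Leaving out each array in turn gave 3944 to 4986 changed probe sets for fresh TI minus fresh TII, 2491 to 3212 for cultured minus fresh TII, and 4543 to 5468 for fresh TI minus cultured TII. Group-specific genes numbered 3006 to 3586, and r was 0.518 to 0.544. With the replicate number as a block the changed probe sets numbered 4787, 2750 and 4754. A floor of 64 was not run, since the values were already log2.

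Of 373 values of named genes, the call was the same for 358 after quantile normalization, 361 with matched spread, 371 with an intensity trend and 339 at an adjusted p under 0.01. Clu, fresh TI minus fresh TII, not called, turned to 0.247 after quantile normalization and 0.087 with matched spread, and ran from -0.164 to 0.022 without 1 fresh TI array, at 0.003 without replicate 3. Cav1, cultured TII minus fresh TII, not called, turned to 0.027 with array weights and ran from -0.166 to 0.101 without 1 cultured array.

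Other probe sets of a named gene that kept the direction gave a difference over 1.5 times smaller in 25 of 76 cases for fresh TI minus fresh TII, 35 of 84 for cultured minus fresh TII and 24 of 70 for fresh TI minus cultured TII. They pointed the other way in 21 values, and the cause was not tested. For fresh TI minus fresh TII they were Acsl4 0.163, Slc12a2 0.299, RT1-Bb 0.006 and 0.293, Cebpd 0.118, Hspa5 0.163, Pdia3 0.177, Ccnd1 0.23, Cebpa 0.075, Id1 0.161 and Ccl2 0.401. For cultured minus fresh TII they were Crp 0.01 and Gnb1 0.945. For fresh TI minus cultured TII they were Me1 0.034, Hspa5 0.003, Tpm1 0.638 and 0.08, Pgk1 0.107, Cebpd 0.041, Cyp51 0.189 and Slc34a1 -0.272.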

Other observations

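This part gives mean log2 values chosen after they were seen, with no explanation. The haemoglobin gene Hbb had a mean of 8.87 in fresh TII, 7.54 in fresh TI and 5.39 in cultured TII cells, with an SD of 0.85 among the fresh TII arrays. The fibrinogen chain Fgg lay at 8.67 in fresh TII, 4.74 in fresh TI and 5.40 in cultured cells, and the iron-binding protein Lcn2 at 9.98, 5.71 and 7.38.

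The growth factor binding proteins formed no single pattern. Igfbp6 lay at 8.92 in fresh TI cells against 6.44 in fresh and 6.03 in cultured TII cells, Igfbp5 at 7.41, 6.62 and 5.40, and Igfbp3 at 5.21, 6.07 and 4.56. Cyclin Ccnd2 lay at 7.28 in fresh TI, 6.09 in fresh TII and 7.71 in cultured TII cells, while the replication clamp Pcna lay at 7.46, 9.13 and 8.45. The 5S rRNA control probe set lay at 7.62 and 7.50 on fresh TII replicates 2 and 4, and at 6.14 and 6.17 on replicates 1 and 3.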
